A study of Nothobranchius furzeri with 10 samples.

How the data were processed

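Brain RNA of 10 male killifish samples was sequenced, 5 with DMSO and 5 with rotenone at 15 pM. Per the labels, total RNA was used and libraries were made with the TruSeq RNA Library Prep Kit v2, which does not mark strand; whether counting used strand is not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be told apart. Genes with near-identical copies are uncertain as well, for a reason that does not depend on strand. The submitters' processing notes name bcl2fastq 1.8.4, STAR 2.4.1d and featureCounts 1.4.6-p4. The genome build and annotation are not given in the sources used here.

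The authors deposited a table of whole-number read counts per gene, not normalized, for 26739 genes in 10 libraries, and a second table of RPKM values (reads scaled by gene length and by library total) of the same genes. The deposited RPKM values were checked against the deposited counts over 14242 genes with more than 50 counts and an RPKM above 1 in every library. If each value had been divided by the total of its own library, counts and RPKM would give 1 length per gene, but the implied lengths varied with a median coefficient of variation of 32.6%. When the 10 totals were instead taken in turn down each column, the coefficient of variation fell to a median of 0.0027% and was under 0.1% in 100% of these genes. The deposited RPKM values are thus between 0.501 and 2 times what the library's own total gives, and 10% of the values were divided by their own total. RPKM therefore entered only alternatives. The gene lengths used here were recovered from this relation for the 22937 genes with counts; 3802 genes had none.

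Samples were grouped by the treatment in their labels. Replicates were numbered in accession order, so a number shared by both groups pairs nothing. The labels do not say whether the samples are separate fish, so p-values measure the spread between these samples. No pair of libraries of a group agreed within sampling noise: chi-square per degree of freedom over genes was 13.7 to 72.7. All columns were mapped to samples.

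The main comparison, rotenone against DMSO, used edgeR 4.0.16 in R 4.3.3: filterByExpr with its defaults (minimum count 10, minimum total 15), TMM scaling, the quasi-likelihood test with its default settings and Benjamini-Hochberg adjusted p under 0.05. This left 19628 genes. The bias-adjusted form of the test was run first, and the default was then made the main test because the design fixed before the data were examined names no other option; the bias-adjusted form is given as an alternative. CPM values were computed from the counts with TMM-scaled library totals. Library measures were compared with exact permutation tests over 252 relabelings. Other permutation tests used 100000 resamples unless stated. The test, the naming rule and the alternatives were fixed before the data were examined, except those named as chosen later in the closing part.

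On counts simulated from these libraries for 19628 genes with 200 changed, edgeR recovered 8% of genes at the smallest simulated fold, 46% at 1.5-fold, 80% at 2-fold and 94% at 4-fold, with 8.8% false calls among 125. DESeq2 recovered 18%, 52%, 94% and 94%, with 26.7% false calls among 176. Each gene was drawn independently around 1 common mean, so the simulation lacks any structure shared across genes, and these shares may not carry over. The median standard error of a log2 fold change was 0.12 over the tested genes.

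The alternatives fixed beforehand were relative log expression and upper-quartile scaling, no filter, a filter of at least 1 CPM in 5 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), robust estimation, 1 surrogate variable (sva 3.50.0), the deposited RPKM as log2(RPKM + 0.1) and log2(RPKM + 1) with limma, and leaving out each library. The surrogate variable was first estimated on counts not scaled for depth; this was corrected to scaled counts, the only values given here.

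None of the 26739 gene identifiers occurs in the reference table of 38438 RefSeq genes (assembly NfurGRZ-RIMD1), so no gene could be named. The 43 gene lists fixed before the data were examined, complex I subunits among them, and their camera tests were therefore not run. The naming rule took genes with an adjusted p under 0.05, a mean of at least 1 CPM, a symbol and groups that do not overlap, ordered by fold change. Without the symbol, 62 higher and 82 lower genes met it, and the first 2 of each direction are given. Figures were drawn with matplotlib 3.10.9.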

Results

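Gene expression was measured by RNA sequencing in the brain of male turquoise killifish (Nothobranchius furzeri), a short-lived annual fish, of the strain MZM-0410p at 27 weeks of age. The labels give 5 samples with DMSO, the solvent used as the control, and 5 with rotenone at 15 pM. Rotenone is an inhibitor of mitochondrial complex I, the entry point of electrons from NADH into the respiratory chain. The labels name neither the length nor the route of the treatment. The total count per library ranged from 15536771 to 31017835 reads with DMSO and from 16693800 to 28047585 reads with rotenone. Between 21575 and 22056 of the 26739 genes in the table had at least 1 count in a library. The same gene was the most abundant in all 10 libraries, with 0.709% to 1.17% of the counts. Neither the totals (two-sided exact permutation p = 0.556) nor the genes detected (two-sided exact permutation p = 0.476) differed between the groups by more than relabeling the samples gave.

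The comparison of rotenone with DMSO asked which genes the exposure changed in the brain. Of 19628 tested genes, 62 were higher and 85 were lower with rotenone, 147 in all, at an adjusted p under 0.05 in edgeR's quasi-likelihood test. The changes were mostly modest: the median absolute log2 fold change of the 147 genes was 0.66, 61 of them changed by less than 1.5-fold and 28 by at least 2-fold. Of those 28 genes, 22 were lower and 6 were higher with rotenone. In 145 of the 147 genes the 5 rotenone values lay entirely on one side of the 5 DMSO values. Among all tested genes this held for 716, or 3.65%, where chance gives 0.794% for a single gene. Genes are not independent: of 100 splits of the libraries into 5 and 5, the labelled one included, 3 gave at least as many such genes, with up to 2072 in another split and a median of 97 over the others. The count depended on single libraries, above all on rotenone replicate 1, without which 2188 genes changed, 1002 of them higher and 1186 lower, with all 147 genes among them in the same direction. It was 29 without DMSO replicate 1, 45 without DMSO replicate 3, 43 without DMSO replicate 4, 37 without DMSO replicate 5, 23 without rotenone replicate 2, 25 without rotenone replicate 3 and 86 without rotenone replicate 5; with 1 surrogate variable it was 240, and DESeq2 called 843 genes, 436 higher and 407 lower, so that the majority turned. By direction, there were 33 higher genes without DMSO replicate 2, 52 higher and 154 lower without rotenone replicate 4, and 25 higher and 61 lower without rotenone replicate 5. Fits without 1 library also have less power, so a fall from 147 need not come from the library left out.

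**Figure D1:**
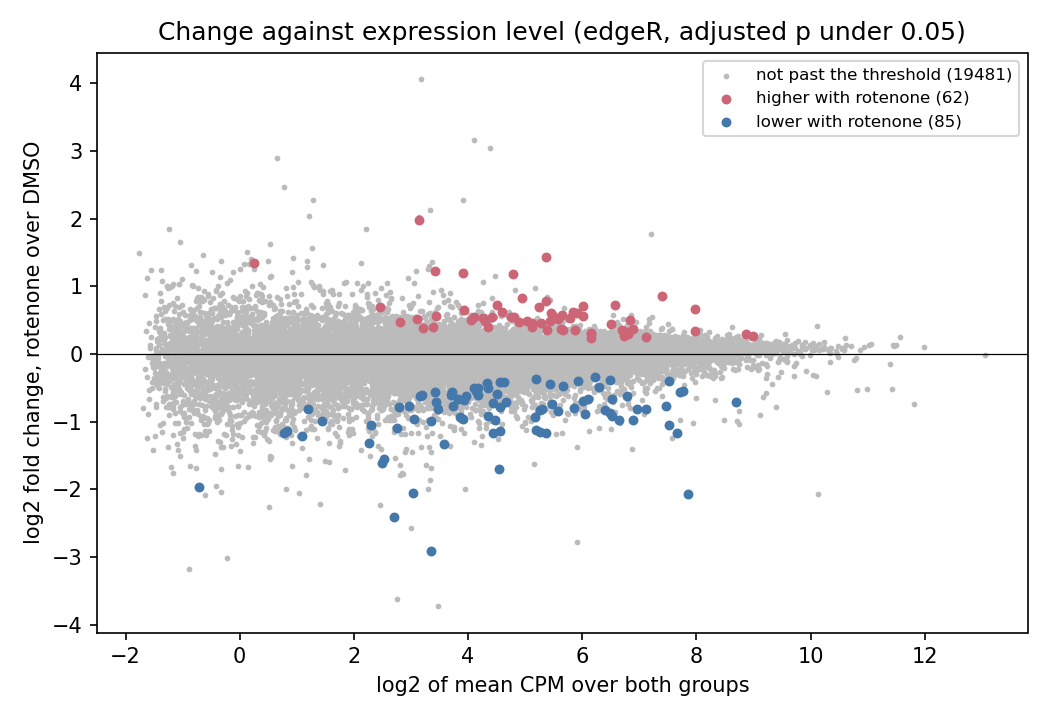
Each point is 1 of the 19628 tested genes, with the log2 of its mean CPM over both groups on the x axis and its log2 fold change, rotenone over DMSO, on the y axis. The 62 higher and 85 lower genes are coloured, and some grey genes with larger fold changes did not pass the test.

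The files identify genes by identifiers and do not pair them with names, so 2 genes that rose and 2 that fell stand here by identifier alone. Nfu_g_1_003210 had the largest rise among the genes that met the naming rule without the symbol. It rose from 3.58 ± 0.657 CPM with DMSO to 14.05 ± 3.52 CPM with rotenone (SD, n = 5 each), a log2 fold change of 1.98 (SE 0.199, edgeR adjusted p = 0.0021). Nfu_g_1_014894 rose from 22.2 ± 3.86 to 59.8 ± 5.00 CPM (SD, n = 5 each), a log2 fold change of 1.43 (SE 0.119), and had an edgeR adjusted p of 0.000544. Its lowest rotenone library, at 53.7 CPM, was above its highest DMSO library, at 26.6 CPM, a gap that the naming rule required.

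Nfu_g_1_009502 fell 7.52-fold, from 17.9 ± 4.61 CPM with DMSO to 2.42 ± 1.249 CPM with rotenone (SD, n = 5 each), a log2 fold change of -2.91 (SE 0.353, edgeR adjusted p = 0.00673). Nfu_g_1_012595 fell 5.28-fold, from 10.9 ± 7.26 to 2.04 ± 0.587 CPM (SD, n = 5 each), a log2 fold change of -2.40 (SE 0.431, edgeR adjusted p = 0.0374). Its DMSO libraries ranged from 4.41 to 22.3 CPM, and all 5 rotenone libraries were between 1.43 and 2.77 CPM. The call of Nfu_g_1_012595 was lost with all 10 libraries in limma-voom (log2 fold change -2.08, adjusted p = 0.0954), and in edgeR without any 1 of 8 libraries: the edgeR adjusted p was 0.0529 without DMSO replicate 2, 0.0547 without DMSO replicate 3, 0.0906 without DMSO replicate 4, 0.0653 without DMSO replicate 5, 0.112 without rotenone replicate 2, 0.124 without rotenone replicate 3, 0.0541 without rotenone replicate 4 and 0.0749 without rotenone replicate 5. Its log2 fold change stayed between -2.54 and -1.97 in these 8 fits.

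**Figure D2:**
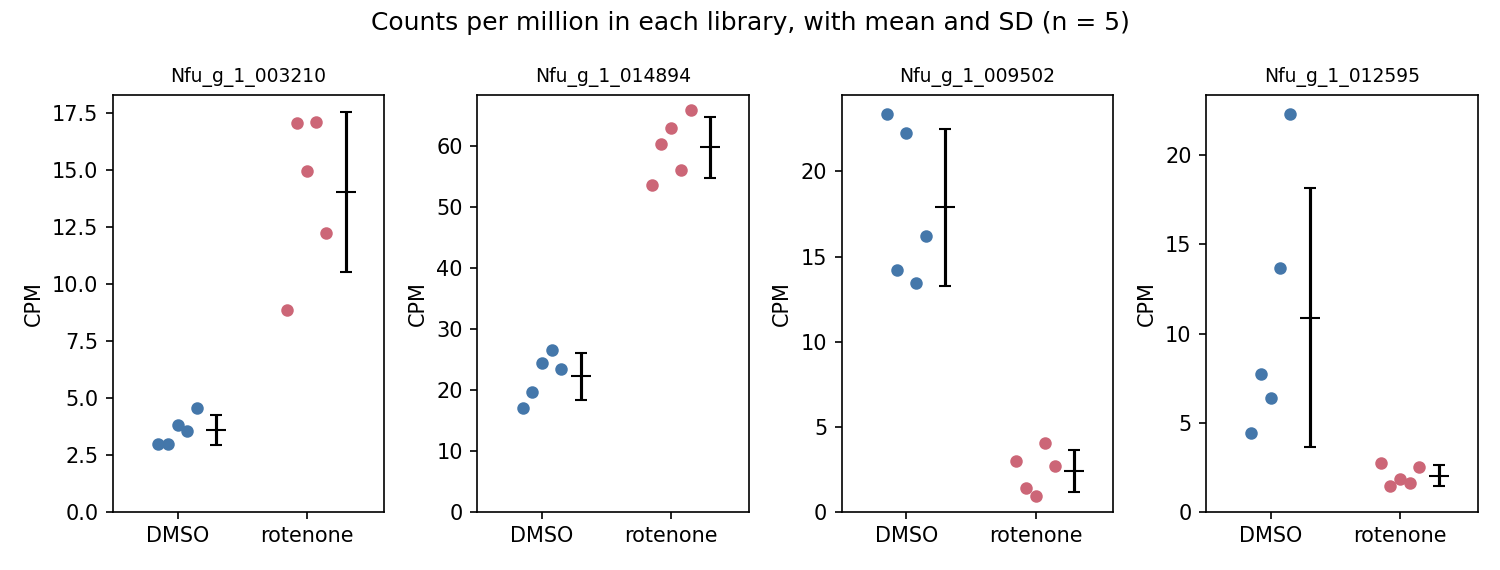
CPM of the 4 genes in each of the 10 libraries (points), with the mean and SD of each group beside them (n = 5). In each gene the rotenone libraries and the DMSO libraries do not overlap, which the naming rule required.

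The median log2 fold change was 0.52 among the higher and -0.80 among the lower genes, and the difference in size was not tested. The median expression was 41.4 CPM for the higher and 22.8 CPM for the lower genes (two-sided permutation p = 0.0244, over genes, which are not independent). Their median lengths, 2873.5 and 3343 bases, did not differ beyond relabeling (two-sided permutation p = 0.417 over the same genes). By level, 99 of the 9994 tested genes between 10 and 100 CPM changed, as did 24 of the 2369 genes at 100 CPM or more, 23 of the 5854 genes between 1 and 10 CPM and 1 of the 1411 genes below 1 CPM.

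The first principal component of the log2 CPM values held 34% of the variance. Rotenone replicates 2 to 5 scored between 23.2 and 48.5 on it, DMSO replicates 1, 2, 3 and 5 between -28.6 and -16.2, DMSO replicate 4 at 5.49 and rotenone replicate 1 at -48.8. The group means on this component, 16.9 ± 38.0 with rotenone and -16.9 ± 13.3 with DMSO (SD, n = 5 each), did not differ beyond relabeling (two-sided exact permutation p = 0.111, 0.278 after Benjamini-Hochberg adjustment over 5 library measures). The second component, with 16.4% of the variance, averaged 14.6 ± 20.6 with rotenone and -14.6 ± 12.9 with DMSO (SD, n = 5 each). Its difference (two-sided exact permutation p = 0.0317) did not pass after adjustment over the same measures (0.159).

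**Figure D3:**
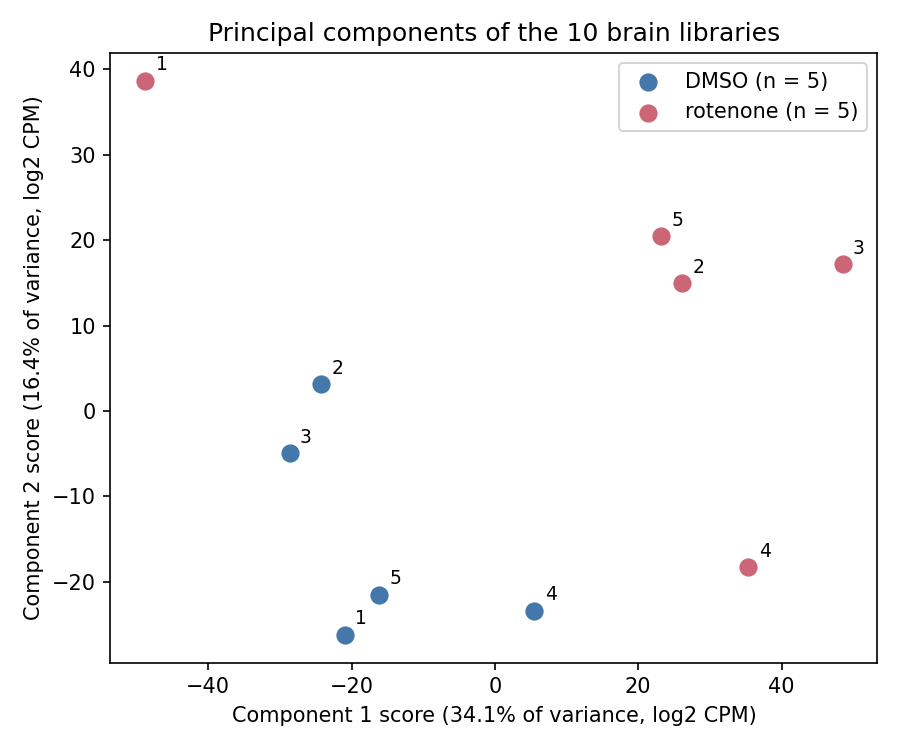
Scores of the 10 libraries on the first (x axis, 34% of the variance) and second (y axis, 16.4%) principal components of log2 CPM, coloured by group and numbered by replicate. Rotenone replicate 1 lies at -48.8 on the first component, apart from the other 4 rotenone libraries.

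**Figure D4:**
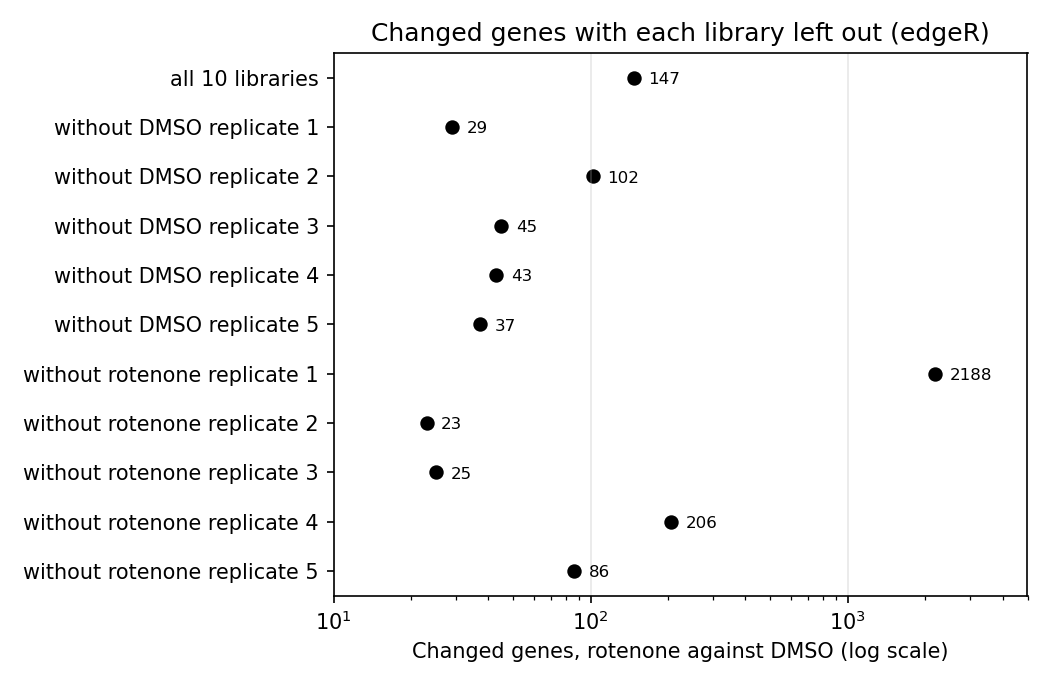
Number of changed genes (edgeR, log axis) with all 10 libraries and with each library left out. The count is 147 with all libraries, 2188 without rotenone replicate 1 and between 23 and 206 without any other library.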

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

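The test of exchanged labels was chosen after related results had been seen, and the splits of the libraries had themselves all been run before their test was written down; those of an untreated fish, length and depth were set before their results. Rotenone replicate 1 had a mean Spearman correlation with the other libraries of its group of 0.9645, where the other rotenone libraries had 0.978 to 0.983, and a score of -48.77 on the first principal component. Both values lay beyond the limit of Dixon's test for an outlying sample. In all, 22 groups of values were tested, and chance marks about 1 in 20.

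With the gene length trend removed from each library, 2438 genes changed without rotenone replicate 1 and 175 with it. With all libraries thinned to the smallest total, the counts were 1679 and 122. Both argue against length bias or depth as the whole cause of the effect of rotenone replicate 1 on the count. Its score on the first component was not recomputed in either setting. Over the 2183 of the 2188 genes called without it that were also tested with all libraries, its median position was -0.116, where 0 is the DMSO mean and 1 the rotenone mean, and 17.4% of these genes lay nearer the rotenone mean. It may have been an untreated fish, and each DMSO library was put in its place to test this. With DMSO replicate 4 there 1621 genes changed, against 43 with rotenone replicate 1 and the same 4 DMSO libraries. DMSO replicate 4 itself lay nearest the other rotenone libraries of all DMSO libraries on the first component, at 5.49. Its join therefore cannot tell how rotenone replicate 1 was treated. DMSO replicates 1, 2, 3 and 5 in place of rotenone replicate 1 each gave at most 1 gene by edgeR, against 29, 102, 45 and 37. These 4 joins run against an untreated fish. The rule set beforehand needed fewer genes with each of the 5 DMSO libraries, and the join of DMSO replicate 4 did not meet it. An untreated fish is therefore left open by that rule. On the second component rotenone replicate 1 lay apart from DMSO, at 38.7, where the DMSO libraries scored -26.2 to 3.16. Rotenone replicate 4, at -18.3, lay among the DMSO libraries, so this component does not separate every library by group.

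Exchanged labels of rotenone replicate 1 and DMSO replicate 4 may also account for it. Over the 2761 of the 2766 genes called with both left out that were also tested with all libraries, DMSO replicate 4 had a median position of 0.442 (quartiles 0.153 and 0.727) and rotenone replicate 1 of -0.147. DMSO replicate 4 thus lay between the groups. It was short of the 0.5 that an exchange was set to need but had an upper quartile above it. That leaves the explanation neither met nor excluded. Rotenone replicate 4 also lay between the groups, with a median position of 0.5 (quartiles -0.13 and 0.977) over the 206 genes called without it. Those 206 genes were called with rotenone replicate 1 as rotenone. Rotenone replicate 4 was not placed over the 2761 genes, so its position cannot tell whether a place between the groups is particular to DMSO replicate 4. On the first component rotenone replicate 4 scored 35.35, between rotenone replicates 2 and 3 at 26.18 and 48.53, and DMSO replicate 4 scored 5.49. The test with both libraries left out replaced an earlier one, also chosen late, that had counted against an exchange. Starting from the exchanged grouping, the labelled grouping gave 147 genes and the 24 other one-for-one exchanges at most 1. Further values run the way the labels say. Over the 43 genes called with DMSO replicate 4 alone left out, its median position was 0.138 (quartiles -0.0502 and 0.354), with 16.3% of these genes nearer the rotenone mean. On the second component it scored -23.4, within the other DMSO libraries, but rotenone replicate 4, at -18.3, lay there too. Of the 147 genes, rotenone replicate 1 lay nearer the rotenone mean in 133 and DMSO replicate 4 in 2. The 43 and the 147 genes were called with rotenone replicate 1 as rotenone, and the 147 with both labels as given, so they cannot decide it. Exchanging the labels gave 2365 genes, 0 of them at an adjusted p under 0.001, against 8 of the 147 as labelled. Differences in dissection, RNA quality or between fish were not tested, and the design has no group that would give a biological explanation to test.

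The labelled grouping gave 147 genes. Of 100 of the 126 splits of the 10 libraries into 5 and 5, 3 gave as many, the labelled one included, a share under the 5% at which chance counts as excluded. Counted by genes at an unadjusted p under 0.05, 6 of the 100 splits gave as many as the 3224 of the labelled one, itself included, which is over that share, so by this count chance is not excluded. These same splits had been seen when that prediction was written, so both are a description of these libraries more than a test, and the count by unadjusted p was looked at later still. The labelled split was not the highest: the highest other, 2365, was the exchange above, and the next, 226, put rotenone replicate 4 with DMSO replicates 1, 3, 4 and 5. A split with several times the labelled count points to a structure of the samples that the groups as labelled do not describe. Exchanged labels, left open above, would also give such a split. In 91 of the other splits no gene passed the threshold.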

How the results depend on the processing

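The alternatives that leave out both libraries, remove the length trend, thin the counts, recompute RPKM or use the bias-adjusted test were chosen after seeing the data. Of 25 alternatives, 12 kept the count of changed genes within 1.5 times of 147. DESeq2 called 843 genes, 436 higher and 407 lower, with 146 of the 147 among them; 698 of its calls were also made by edgeR without rotenone replicate 1. With 1 surrogate variable 240 genes changed, 98 higher and 142 lower. The bias-adjusted test, run before the default, gave 158. The deposited RPKM gave 0 changed, 0 higher and 0 lower genes with limma at either pseudocount, with 1215 and 1206 genes at an unadjusted p under 0.05, against 3224 for edgeR on the counts. Without both rotenone replicate 1 and DMSO replicate 4, 2766 genes changed, 1202 higher and 1564 lower. On the surrogate variable rotenone replicate 1 had the largest value, 0.643, and the other libraries lay between -0.425 (rotenone replicate 3) and 0.286 (DMSO replicate 3). The causes of the DESeq2 and surrogate variable differences were not tested.

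Leaving out 1 library, which also lowers power, gave 23 to 2188 changed genes, 11 to 1002 higher and 12 to 1186 lower. The counts were 29, 45, 43 and 37 without DMSO replicates 1, 3, 4 and 5, 2188 without rotenone replicate 1, and 23, 25 and 86 without rotenone replicates 2, 3 and 5. Without DMSO replicate 2 there were 33 higher genes, without rotenone replicate 4 there were 52 higher and 154 lower (74.8% lower against 57.8% with all libraries), and without rotenone replicate 5 there were 25 higher and 61 lower (70.9% lower). The 4 named genes kept their direction in all 100 values and passed the threshold in 83. Nfu_g_1_012595 passed in 14 of 25 alternatives, not in limma-voom, the deposited RPKM or 8 of the fits without 1 library, and each of the other 3 genes in 23 of 25, lost only with the deposited RPKM. The gene list medians and list tests planned were not run, since no identifier could be paired with a name here. No paired analysis was possible because replicate numbers follow accession order. In the simulation edgeR recovered 46% of genes with a 1.5-fold change and 8% at the smallest fold, so many small changes may go undetected. The simulated genes were drawn independently, without the structure these libraries share across genes, so the recovered shares may not carry over.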

Other observations

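The test of the RPKM totals was set before its result; the tests of adjacent genes, of the variance and of library measures were chosen after seeing the data. Changed genes lay next to each other in the count table more often than random draws gave. There were 5 adjacent pairs among the 147, where 10000 random draws of tested genes averaged 0.878 (permutation p = 0.0024), and both genes of all 5 pairs changed in the same direction. These pairs prompted the test, so its p describes this table; random placement alone rarely gave as many. Whether the order of the table follows the genome is not given in the sources used here, so shared regulation of neighbouring genes, split gene models and gene copies that share reads stay open and untested. Across 15644 pairs of neighbouring tested genes, which are not independent, the Spearman correlation of log2 fold changes was 0.105.

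Library totals taken in turn down the columns may account for the absence of calls from the deposited RPKM. Recomputed with each library's own total, RPKM gave 127 changed genes with limma, 116 of them among the 147 and in the same direction, where the deposited values gave 0 (1215 at an unadjusted p under 0.05) and edgeR on the counts gave 147.

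The variance between libraries was higher with rotenone, with a median log2 ratio to DMSO over genes of 0.81 (two-sided permutation p = 0.0635 over 252 relabelings), which did not pass. The relabeled values were first centred on the mean of their group, so this p is approximate. Without rotenone replicate 1 the ratio was 0.09. There were 9 genes above 5 CPM in at least 2 libraries and below 0.2 CPM in at least 2 others; 0 of them changed between the groups in edgeR's test, and 6 showed both states in both groups. Of 3 library measures set against the first principal component (n = 10), the share of the most abundant gene had Pearson's r = -0.716 (permutation p = 0.0194, 0.0582 after Benjamini-Hochberg adjustment) and Spearman's rho = -0.588 (permutation p = 0.0811). The 2 libraries farthest from the median share were rotenone replicate 1, at 1.165%, and DMSO replicate 3, at 1.07%. Without them r was -0.406, so the relation rests in part on those libraries. None of the 3 measures passed after adjustment.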
